A study of Arabidopsis thaliana with 19 samples.

How the data were processed

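RNA from 19 single Arabidopsis seedlings was hybridised to Affymetrix ATH1 arrays, 1 array per seedling. Per the labels' protocols, seedlings grew on Murashige and Skoog medium in a growth chamber, and RNA was extracted with Trizol, cleaned on a column and labelled with biotin by a 3' IVT kit. Per the submitters' processing notes, the deposited log2 values were made with RMA, which corrects the background, normalizes quantiles between arrays and summarises probes to 1 value per probe set. The version of RMA was not given in the sources used here. Scanner files were not used here. The values ranged from about 2 to about 14, with none missing (0). For arrays, their number limits the precision.

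The table held 22810 probe sets, of which 64 controls were set aside and 22746 tested. The platform annotation listed 14016 of the table's probe sets, 13513 with 1 gene and 503 with several, and did not list 8730. Symbols of 13436 single-gene probe sets were updated through a gene table of the TAIR10.1 assembly, which also gave the chromosome and the neighbours of each gene. No coordinates are printed, because the array values name no genome build. The single-gene probe sets covered 13356 genes, 146 of them by more than 1 probe set. A probe set that the annotation does not list is unnamed here, which does not mean that it lacks a gene.

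Groups were compared with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 19 seedlings and no block, empirical Bayes moderation and Benjamini-Hochberg adjustment over the 22746 probe sets. A probe set was called at an adjusted p under 0.05, and every adjusted p given for a gene comes from this fit unless another is named. There were 6 comparisons between groups, 2 of a triploid with the mean of the diploid and tetraploid group means on the log2 scale, and a slope on genome copies with both triploids at 3. These comparisons, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. Single-gene probe sets that passed were named by the largest changes, up to 10 per direction for the comparisons with diploids and between the triploids and up to 3 for the others. Where fewer than 3 passed, the 3 with the smallest p were named too, as not passing. From each list up to 4 members per comparison with the smallest p could be named, and up to 2 unnamed probe sets per direction.

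The 33 fixed lists held 529 loci, 67 of them with a single-gene probe set. Of these lists 6 had no measured member, 12 had 1 or 2 and 15 had at least 3 and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A gene with several probe sets entered by the brightest. Wider lists (16 by theme, and 28 families of at least 8 genes sharing a symbol) were added after the data were seen. The families between the triploids are not reported here. Shifts of chromosomes were medians over single-gene probe sets of the log2 value minus the probe set's median over all arrays, minus the same median over all 5 nuclear chromosomes. Bright probe sets were the brightest 30%. Group means of single values were compared with exact two-sided permutation tests. Whether a measure per array followed the replicate number was tested, after the data were seen, on values minus their group mean with 100000 permutations of the numbers within groups. Comparisons that share the diploid arrays were set beside 100 simulations of unchanged groups with a shared control, and beside all 6 splits of the 4 diploids.

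The alternatives were only the compared groups in the fit, eBayes with trend and robust, leaving out the dimmest 30% of probe sets (below a mean of 4.07), a further quantile normalization, array weights, a block for the replicate number, 1 probe set per gene, a fold of at least 1.5, leaving out each seedling, the trend with 1 kind of triploid, the mean of a gene's probe sets, a mean trimmed by 10%, windows of 100 neighbouring genes and the 4 diploid arrays as reference. Leaving out the seedling with higher chromosome 4 was added after the data were seen. The fits were tested on simulated data of 22746 probe sets with 50 changed per fold. In 4x minus 2x 64% were recovered at a fold of 1.5 and 92% at a fold of 2, with 12 false calls. In 3xm minus 2x these shares were 48% and 82%, with 7 false calls. In 3xp minus 2x they were 68% and 86%, with 7 false calls, and in 3xp minus 3xm 48% and 86%, with 8. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.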

Results

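Transcript levels were measured in 19 single seedlings of Arabidopsis thaliana, a small self-fertilising crucifer, at an age of 2 weeks. The seedlings formed an autopolyploid series, in which all genome copies come from 1 species. Diploids (2x) were represented by 4 seedlings, and 5 seedlings each were tetraploids (4x), triploids with an excess of maternal genomes (3xm) and triploids with an excess of paternal genomes (3xp). Both triploids carry 3 genome copies and differ in which parent contributed the larger number. Each seedling gave 1 Affymetrix array of 22810 probe sets, deposited as log2 expression values whose median lay between 5.80 and 5.89 on every array. The closest pair of arrays differed by a root mean square of 0.231, so no array was a duplicate of another. Because every array was brought to 1 distribution, the values show changes relative to the rest of the transcriptome, not amounts per cell or per genome copy. Differences are given on the log2 scale as the first group minus the second, ± SE from limma, and group levels as the mean ± SD.

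**Figure D1:**
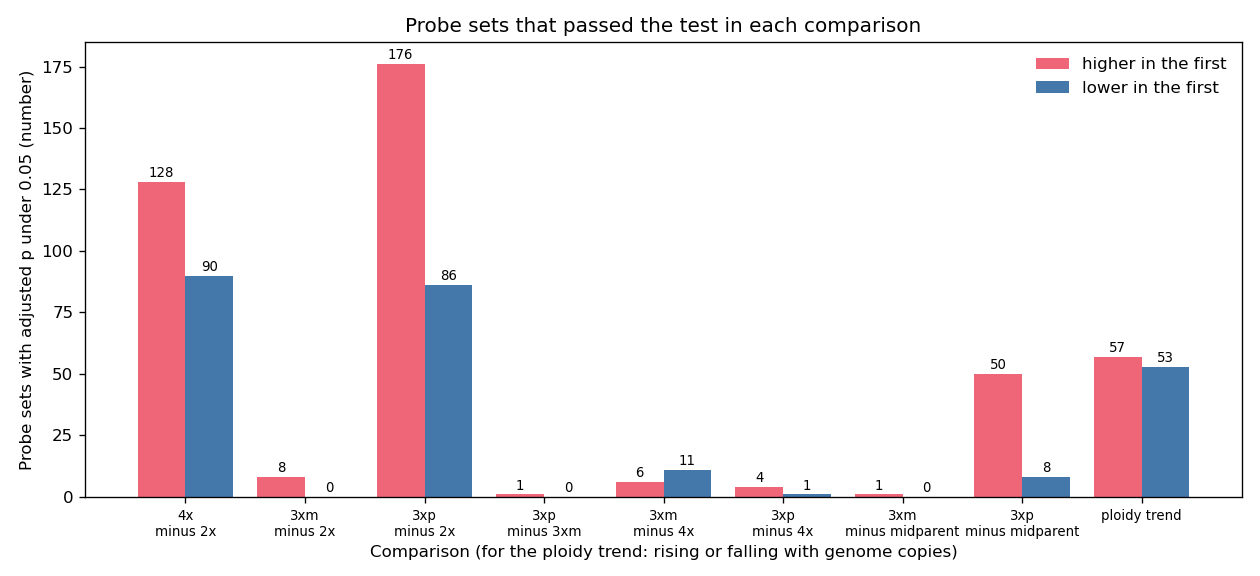
Number of probe sets (y axis) that passed the test at an adjusted p under 0.05 in each comparison (x axis), with bars for those higher and those lower in the first group, or rising and falling with genome copies for the trend. The tallest bars belong to 3xp minus 2x (176 higher, 86 lower) and 4x minus 2x (128 higher, 90 lower), while 3xp minus 3xm has 1 probe set.

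Tetraploids against diploids addressed what a doubling of the whole genome does to a seedling's transcripts. XTH26, a xyloglucan endotransglucosylase/hydrolase of the cell wall, rose by 2.62 ± 0.523 in the tetraploids, from 5.38 ± 0.45 (SD, n = 4) to 8.0 ± 0.54 (SD, n = 5) (limma, adjusted p = 0.0172). AT3G15450 rose by 2.53 ± 0.415 (adjusted p = 0.00462) and AT2G20670 by 2.21 ± 0.293 (adjusted p = 0.000791). SIS, named for its salt induction, rose by 1.77 ± 0.302 (adjusted p = 0.00583). AT5G25280 rose from 9.14 ± 0.47 to 10.89 ± 0.12, a difference of 1.75 ± 0.181 (adjusted p = 5.25e-05). The other named rises were AT4G11190 (2.18), AT5G19120 (2.11), AT1G12030 (1.81), AT5G60680 (1.68) and AT3G07350 (1.59). Among the genes that fell was IAGLU, a glucosyltransferase acting on the auxin indole-3-acetate, with a difference of −0.74 ± 0.119 (adjusted p = 0.00443) from 8.79 ± 0.10 in the diploids. AT3G01260 had the largest named fall, −1.86 ± 0.402 (adjusted p = 0.0301). It was followed by AT1G73120 (−1.39), AT2G23910 (−1.28), AT3G44450 (−1.25) and AT5G62210 (−1.20), and by AT5G15950, AT4G19370, AT1G32690 and AT5G02180 between −0.90 and −0.84. For XTH26 and IAGLU the diploid and tetraploid seedlings did not overlap. Larger changes were seen for probe sets that the annotation used here does not name: 252367_at rose by 3.22 ± 0.335, and 253502_at and 248048_at fell by 4.06 and 3.54. Over all 22746 probe sets tested, 218 passed, 128 higher and 90 lower in the tetraploids. The count was 77 without seedling 2x 1, 135 without 2x 4, 382 without 3xm 4, 138 without 4x 1, 131 without 4x 4, 125 without 4x 5, 451 with the triploids left out of the fit and 1017 with array weights, of which 466 were higher and 551 lower. Omitting 2x 1 also ended the calls of XTH26, AT1G12030, AT3G07350 and AT4G19370, omitting 4x 1 or 4x 5 ended that of XTH26, omitting 2x 1, 2x 4, 4x 1 or 4x 5 ended that of AT5G02180, and the calls of AT4G11190 (14), AT1G32690 (14), AT5G15950 (13), AT1G73120 (9) and AT3G01260 (7) ended in the number of the 19 omissions given, those of AT4G11190 and AT1G73120 also with eBayes trend and robust, and those of AT5G15950 and AT1G32690 with 1 probe set per gene.

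Of the gene groups fixed beforehand, the genes encoded in the plastid stood higher in the tetraploids as a set, with the preset correlation only. Of 69 measured plastid genes 68 had a positive difference, with a median of 0.325, and camera gave an adjusted p of 2.53e-12 with its preset correlation between genes. The correlation estimated for this list was 0.534, far above the preset value, and the same in the other comparisons tested. With it camera gave an adjusted p = 0.931. The small p with the preset thus rests on treating these genes as nearly independent. None of the 69 passed the test by limma on its own, and 0 did when adjusted over the list alone. The largest differences were psaI of photosystem I (0.84 ± 0.266, adjusted p = 0.154) and petL of the cytochrome b6f complex (0.82 ± 0.273, adjusted p = 0.173), which both passed without seedling 2x 3 or with array weights. The 3 measured root markers were also higher as a set, with a median of 0.847 (adjusted p = 0.0215 with the preset correlation, adjusted p = 0.37 with an estimated correlation). EXPA18 differed by 1.11 ± 0.394, EXPA7 by 0.85 ± 0.475 and PYK10 by 0.22 ± 0.0889; none passed over all probe sets and 2 passed when adjusted over the list alone. The root set lost its call without seedling 2x 2 (adjusted p = 0.0605), 2x 3 (0.107), 4x 1 (0.0842) or 4x 5 (0.0639), and the number of sets passing then was 1 instead of 2. In the flavonoid and anthocyanin list UGT78D2, a flavonoid glucosyltransferase, fell by 0.71 (SE 0.15, adjusted p = 0.0254), a call that ended without 2x 1, 2x 3, 2x 4, 4x 4 or 4x 5. UGT78D1 differed by −0.63 ± 0.151 (adjusted p = 0.0536), and the other 4 members did not pass, with 2 passing when adjusted over the list alone. As a set this list passed only without 2x 1 (median −0.509, adjusted p = 0.0014) or 4x 2 (median −0.208, adjusted p = 0.0396). Both handling-response genes measured had positive differences that did not pass, WRKY53 with 1.4 ± 0.576 and STZ with 0.63 ± 0.345. The 6 nuclear photosynthesis genes (median 0.0468), 5 ribosomal genes (median 0.00446), 5 cell wall expansion genes (median −0.137), 3 mitotic genes (median 0.273) and 11 mitochondrial genes (median 0.00325) did not pass as sets, and none of their members did. The other tested lists did not pass either.

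Maternal-excess triploids against diploids asked the same of 1 added maternal genome. AT2G20670 rose by 1.90 ± 0.293, from 6.86 ± 0.54 (SD, n = 4) to 8.75 ± 0.43 (SD, n = 5) (limma, adjusted p = 0.0155). AT5G60680 and AT2G27830 each rose by 1.32 (SE 0.197 and 0.195, adjusted p = 0.0114 for both). AT1G23710 rose by 0.85 ± 0.126 (adjusted p = 0.0114) and AT4G05070, on chromosome 4, by 0.91 ± 0.158 (adjusted p = 0.0465). Seedling 3xm 4 had higher levels of chromosome 4 genes than the other seedlings, a median shift of 0.125 over that chromosome. Among unnamed probe sets, 267139_s_at rose by 1.88 ± 0.188 and 254919_at by 0.87 ± 0.137. In total 8 probe sets passed by limma, all higher in the triploids, and 985 had an unadjusted p under 0.05 where 1137.3 were expected by chance. The count was 1 without 2x 1, 13 without 2x 2, 4 without 2x 3, 17 without 2x 4, 1 without 3xm 2 and 0 when only these 2 groups were fitted, which left an adjusted p of 0.373 for each of the 5 genes. Omitting 2x 1 or 3xm 2 ended the call of each of the 5 genes, omitting 2x 3 or 3xm 3 that of AT2G20670, and that of AT4G05070 ended in 14 of 19 omissions, including that of 3xm 4, and with array weights or a further normalization.

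As in the tetraploids, the plastid-encoded genes were higher as a set in the maternal-excess triploids with the preset correlation only. Of the 69, 66 had a positive difference and the median was 0.345 (camera, adjusted p = 1.43e-22 with the preset correlation, adjusted p = 0.476 with an estimated correlation). No member passed by limma, over all probe sets or adjusted over the list alone. The subunit gene rbcL of the carbon-fixing enzyme Rubisco differed by 0.55 ± 0.188 and rps4, for a ribosomal protein, by 0.55 ± 0.194, both with an adjusted p of 0.999. Of the 15 lists tested this was the 1 that passed, and there were 2 without 2x 1 or 3xm 4, with the auxin-response list (adjusted p = 0.0323 and 0.025), and 3 without 2x 3, with the genes imprinted in endosperm (0.0133) and the mitochondrial genes (0.0323). Both handling-response genes passed when adjusted over the list alone, STZ with 1.32 ± 0.345 and WRKY53 with 1.28 ± 0.576, but not over all probe sets. All 5 auxin-response genes had positive differences (median 0.197) that did not pass. The 3 root markers differed by a median of 0.0376 and the 6 flavonoid genes by 0.328, neither passing, and the other tested lists did not pass.

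Paternal-excess triploids against diploids asked the same of 1 added paternal genome. AT3G15450 rose by 3.38 ± 0.415, from 6.51 ± 1.05 (SD, n = 4) to 9.88 ± 0.52 (SD, n = 5) (limma, adjusted p = 0.000274), and AT2G20670 by 2.66 ± 0.293 (adjusted p = 0.000112). STZ, a zinc finger transcription factor of salt and other stress responses, rose by 1.94 ± 0.345 (adjusted p = 0.00757), and SIS by 2.12 ± 0.302 (adjusted p = 0.000985). AT5G61590, also called DEWAX after its part in limiting wax synthesis, rose by 1.56 ± 0.262 (adjusted p = 0.00458). AT2G27830 rose by 2.04 (adjusted p = 3.34e-05), and AT5G19120 (2.14), AT5G60680 (1.89), AT3G07350 (1.83) and AT3G10020 (1.80) also rose. Named falls were smaller. AT2G27420 fell by 1.35 (SE 0.287, adjusted p = 0.0245), AT4G16563 by 1.11 (SE 0.2, adjusted p = 0.00782) and IAGLU by 0.64 (SE 0.119, adjusted p = 0.0101). The others were AT1G23205 (−1.06), AT2G23910 (−1.03), AT2G44940 (−0.92), AT5G17270 (−0.83), AT4G19370 (−0.77), AT3G17130 (−0.57) and AT1G65920 (−0.55). Among unnamed probe sets, 252367_at rose by 2.78 and 253161_at by 2.76, and 245553_at and 256459_at fell by 1.54 and 1.14. In total 262 probe sets passed, 176 higher and 86 lower. The count was 107 without 2x 1, 154 without 2x 3, 149 without 2x 4, 158 without 3xp 1, 163 at a fold of at least 1.5 (without AT3G17130 and AT1G65920), 423 with array weights, and 109 with only these 2 groups in the fit, which ended the calls of AT3G07350, AT5G61590, AT1G23205, AT2G23910, AT2G44940, AT5G17270, AT4G19370 and IAA29. Omitting 2x 1 ended the calls of AT5G17270 and AT3G17130, and of the 19 omissions 14 ended that of AT4G19370, 12 that of AT1G23205, 7 that of AT1G65920 and 6 each those of AT2G27420 and AT2G23910.

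The fixed groups behaved as follows in the paternal-excess triploids. Plastid-encoded genes had a median difference of 0.233, with 66 of 69 positive (camera, adjusted p = 6.69e-07 with the preset correlation, adjusted p = 0.818 with an estimated correlation). Without 2x 1 the median was 0.0607 (adjusted p = 0.289), and the flavonoid list passed in its place, with a median of −0.351 (adjusted p = 0.0329) instead of 0.11. No plastid gene passed by limma, over all probe sets or adjusted over the list alone, and rps4 differed by 0.45 ± 0.194 and rpl33 by 0.31 ± 0.126. In the auxin-response list IAA29, an Aux/IAA repressor, rose by 1.55 ± 0.369 (adjusted p = 0.0481), also when adjusted over the list alone, but the call ended in 15 of the 19 omissions, with eBayes trend and robust (adjusted p = 0.0619) and with 1 probe set per gene (adjusted p = 0.052). Of the handling-response genes STZ passed, WRKY53 differed by 1.71 ± 0.576 without passing, and 2 passed when adjusted over the list alone. UGT78D2 differed by −0.62 ± 0.15 (adjusted p = 0.0506) and UGT78D1 by −0.46 ± 0.151 (adjusted p = 0.187). DME, a DNA glycosylase that removes methylated cytosine, differed by −0.41 ± 0.125, with 1 of 1 passing when adjusted over the list alone and an adjusted p of 0.15 over all probe sets. As the 1 measured member of its list, it was left unadjusted by the former. The 3 root markers had a median of 0.4 and did not pass as a set, nor did the other tested lists.

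**Figure D2:**
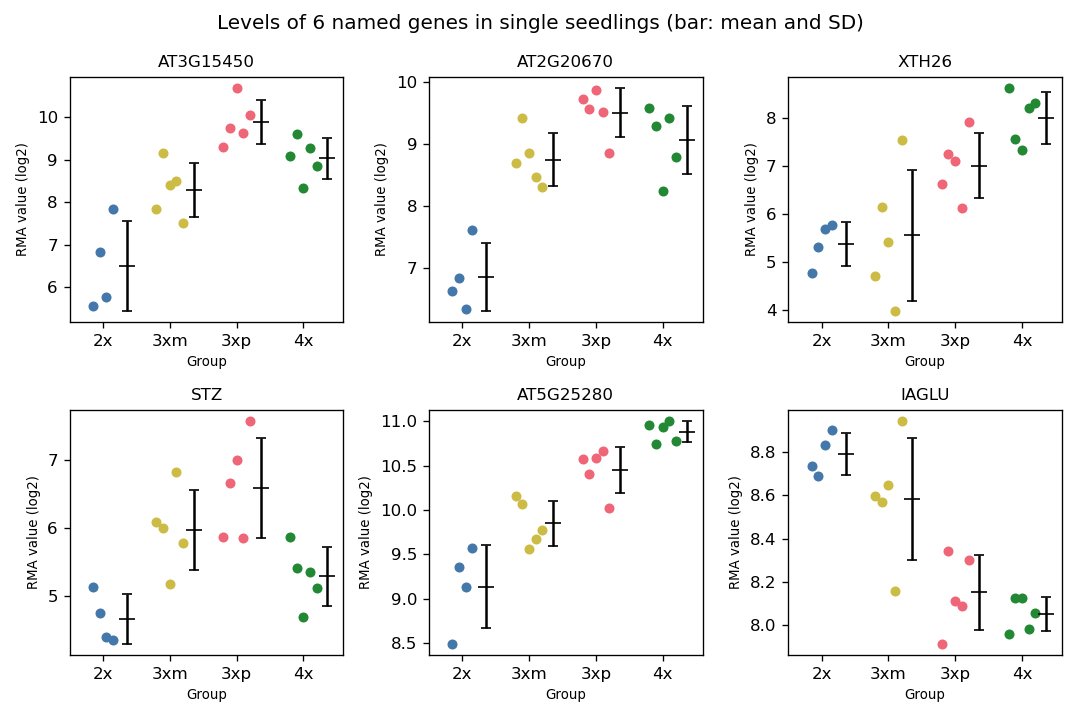
Log2 expression (y axis) of 6 named genes in each seedling, by group (x axis: 2x, n = 4, and 3xm, 3xp and 4x, n = 5 each), with points for seedlings and a black bar with whiskers for the mean and SD. AT3G15450 averaged 6.51 in 2x, 8.29 in 3xm, 9.88 in 3xp and 9.04 in 4x, whereas IAGLU averaged 8.79, 8.58, 8.15 and 8.05.

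The reciprocal triploids have the same number of genome copies and differ in which parent gave the extra one. Anything else that differs between the reciprocal crosses goes with it and was not separated. The probe set 245668_at, which the annotation used here does not name, was higher in the paternal-excess triploids by 0.88 ± 0.114 (limma, adjusted p = 0.00731). Its level was 5.87 ± 0.17 (SD, n = 5) against 4.98 ± 0.16 (SD, n = 5), and 4.60 in diploids and 5.34 in tetraploids. Next in p, without passing, were AT1G05575 with 0.98 ± 0.157 (adjusted p = 0.0698) and AT5G11090 with 0.59 ± 0.107 (adjusted p = 0.167). DME differed by −0.52 ± 0.118, with an adjusted p of 0.383 over all probe sets. It passed when adjusted over its list alone, but it was the 1 measured member there, so that adjustment changed nothing. IAA29 differed by 1.15 ± 0.348 (adjusted p = 0.704) and passed when adjusted over its list of 5 measured genes alone. Plastid-encoded genes were lower as a set with the preset correlation only. Of the 69, 17 were positive and the median was −0.0736 (camera, adjusted p = 0.0319 with the preset correlation, adjusted p = 0.948 with an estimated correlation). All 4 cold and abscisic acid genes had positive differences (median 0.437, adjusted p = 0.0964), among them COR15A with 0.95 ± 0.621, and all 6 flavonoid genes negative ones (median −0.242, adjusted p = 0.129). The 3 genes imprinted in endosperm had a median of −0.0999 and none passed, nor did the other tested lists. Seedling 3xm 4 enters this comparison with its higher chromosome 4. In all 1 probe set passed and 1386 had an unadjusted p under 0.05. The count was 2 without 2x 1, 3xp 5, 4x 1 or 4x 3, 4 without 3xm 2, and 0 with only the triploids in the fit, where 245668_at had an adjusted p of 0.0867. Of the fixed lists 0 passed without 3xm 1, 3xm 2, 3xm 4, 3xp 1 or 3xp 5 or without dim probe sets, and 2 passed without 3xm 3 (the cold and flavonoid lists, adjusted p = 0.0105 for both), 3xm 5 or 3xp 3 (the cold list beside the plastid set, adjusted p = 0.0237 and 0.0389). The call of the plastid set also ended without 3xm 3.

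Against the tetraploids, the maternal-excess triploids differed most in AT4G33720. This gene, on chromosome 4, was lower (−3.82 ± 0.532, limma, adjusted p = 0.00449), at 5.35 ± 0.49 (SD, n = 5) against 9.17 ± 1.05 (SD, n = 5), while diploids averaged 6.88. AT5G25280 (−1.04 ± 0.171, adjusted p = 0.0219) and AT5G23840 (−0.87 ± 0.137, adjusted p = 0.0148) were lower as well. Of the unnamed probe sets, 251436_at was higher by 1.19 and 252367_at was lower, at −2.14. Seedling 3xm 4, with its higher chromosome 4, belongs to this group. In all 17 probe sets passed, 6 higher and 11 lower. The count was 11 without 2x 4, 10 without 3xm 1, 6 without 3xm 3, 56 without 3xm 5, 10 without 4x 1, 6 without 4x 4, 8 without 4x 5, 11 at a fold of at least 1.5 and 45 with array weights (22 higher, 23 lower). Without 3xm 4, 22 passed, 15 higher and 7 lower, among them 11 of the 17. The call of AT5G25280 ended without 3xm 3, 4x 1, 4x 4 or 4x 5, and that of AT5G23840 without 3xm 1, 3xm 3 or 4x 4 and with only these groups fitted (adjusted p = 0.153).

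In the paternal-excess triploids AT5G23840 was again below the tetraploid level, with a difference of −0.91 ± 0.137 (limma, adjusted p = 0.0216), at 3.21 ± 0.15 (SD, n = 5) against 4.12 ± 0.32 (SD, n = 5). As one of the dimmest 30% of probe sets (below a mean of 4.07), it drops out when these are left out, and the size of its difference is uncertain. The unnamed 251436_at was higher by 0.74 ± 0.0829 and 252474_at by 0.66 ± 0.0763 (adjusted p = 0.000747 for both). These are among 5 probe sets that passed, 4 higher and 1 lower, and 1105 had an unadjusted p under 0.05 where 1137.3 were expected by chance. The count was 3 without 2x 2, 2x 3, 2x 4, 3xm 2, 3xm 3, 3xm 4, 3xp 1 or 3xp 4, 2 without 3xp 2, 3xp 3, 4x 3, 4x 4 or 4x 5, and 1 with only these groups fitted. The call of AT5G23840 ended without 3xp 1, 3xp 2, 3xp 3, 4x 3, 4x 4 or 4x 5 and, like that of 252474_at, with only these groups fitted (adjusted p = 0.172 and 0.0504).

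Each triploid was set against the midpoint of diploids and tetraploids on the log2 scale, which serves as a reference only. Where these groups differ, a transcript midway between them on the linear scale lies above that midpoint, so a value above it does not by itself depart from proportion to genome copies. In the paternal-excess triploids AT3G15450 exceeded it by 2.11 ± 0.346 (limma, adjusted p = 0.0128), STZ by 1.62 ± 0.288 (adjusted p = 0.0201) and AT2G20670 by 1.55 ± 0.245 (adjusted p = 0.0103). STZ stood at 6.59 ± 0.74 (SD, n = 5), above the means of both diploids (4.65) and tetraploids (5.29), though its difference from the tetraploids did not pass. AT5G17270 (−0.68 ± 0.135, adjusted p = 0.0364) and AT1G80720 (−0.38 ± 0.0736, adjusted p = 0.0343) fell below it. In all 58 probe sets passed, 50 above and 8 below the midpoint. The count was 34 without 2x 1, 37 without 2x 3, 17 without 3xp 1, 26 without 3xp 2 or 3xp 3, 31 without 4x 3, 37 without 4x 5 and 88 with array weights. The call of STZ ended without 3xp 2 or 3xp 3, that of AT5G17270 in 12 and that of AT1G80720 in 11 of the 19 omissions, both also with the other triploids left out of the fit, that of AT5G17270 with array weights (adjusted p = 0.0563) and that of AT1G80720 at a fold of at least 1.5.

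For the maternal-excess triploids 1 probe set passed against the midpoint. It was 251436_at, without a gene in the annotation used here, at 0.51 ± 0.0733 above it (limma, adjusted p = 0.039), with group levels of 6.22 in 2x, 6.04 ± 0.15 (SD, n = 5) in 3xm and 4.85 in 4x. The next in p did not pass: 252474_at with 0.41 ± 0.0674 (adjusted p = 0.0973) and AT4G33720 with −2.68 ± 0.47 (adjusted p = 0.15). The higher chromosome 4 of seedling 3xm 4, which carries AT4G33720, applies here too. There were 823 probe sets at an unadjusted p under 0.05, below the 1137.3 expected by chance. The count was 0 in 16 of the 19 omissions (all but 2x 4, 3xm 4 and 3xp 3), with only these groups fitted, with eBayes trend and robust and at a fold of at least 1.5.

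Across the series, among named genes that passed the trend test, 3 with the steepest rise per added genome copy were AT5G19120 (1.01 ± 0.219, limma, adjusted p = 0.0414), AT1G12030 (0.94 ± 0.191, adjusted p = 0.0285) and AT5G25280 (0.87 ± 0.114, adjusted p = 0.00172). AT5G25280 stood at 9.14 in 2x, 9.85 in 3xm, 10.46 in 3xp and 10.89 in 4x. The others were less graded: AT5G19120 stood at 7.96, 9.66, 10.10 and 10.07, and AT1G12030 at 6.58, 6.74, 7.0 and 8.40. The steepest falls among them were AT1G73120 (−0.70 ± 0.152, adjusted p = 0.0403), AT3G44450 (−0.63 ± 0.116, adjusted p = 0.0205) and AT2G23910 (−0.62 ± 0.12, adjusted p = 0.0242). The unnamed 252367_at rose by 1.59 per copy, and 253502_at and 248048_at fell by 2.06 and 1.78. In all 110 probe sets passed, 57 rising and 53 falling. The count was 25 without 2x 1, 68 without 2x 2, 46 without 2x 3, 34 without 2x 4, 226 without 3xm 4, 50 without 4x 1, 48 without 4x 2, 47 without 4x 4, 33 without 4x 5, 29 at a fold of at least 1.5, 683 with array weights (296 rising, 387 falling), 223 with 3xm and 186 with 3xp as the triploid. AT5G19120 and AT1G73120 lost their calls in 11 of 19 omissions each, AT1G12030 in 7, AT2G23910 in 5 and AT3G44450 without 2x 4 or 4x 4, and AT5G19120 also with eBayes trend and robust and with 3xp as the triploid.

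Differences of the polyploid groups from the diploids resembled each other across probe sets, which are not independent replicates. Among the genes higher in both 3xp and 4x were AT3G15450, AT2G20670, SIS, AT5G19120, AT5G60680 and AT3G07350, and IAGLU, AT2G23910 and AT4G19370 were lower in both. In total 76 probe sets were higher and 25 lower in both, where independent lists of the same lengths would share 0.99 and 0.34. AT2G20670, AT5G60680 and AT2G27830 were higher in both triploids. All 8 probe sets called in 3xm were also called higher in 3xp and in 4x, where independent lists would share 0.0619 and 0.045. The correlation of differences was 0.751 for 3xp and 4x, 0.695 for 3xm and 3xp, and 0.633 for 3xm and 4x. These comparisons share the 4 diploid arrays. In 100 simulations, deviations of arrays from their group means were drawn with replacement from all seedlings, for unchanged groups and a shared control of 4. The correlation was then 0.508 on average, with a central range from −0.0178 to 0.869. An array could be drawn more than once and the control was not limited to diploids, so these ranges are only a guide. The covariance was 0.0446, 0.0307 and 0.0292 in that order, against 0.0154 simulated on average. The upper end of its central range was 0.0429, which the values of 3xm with 3xp and of 3xm with 4x did not exceed. With 2 different diploids in each comparison the correlation averaged 0.434, 0.307 and 0.269 over 6 splits, and the shared calls of 3xp and 4x were 15 to 28 higher and 1 to 3 lower. Those of 3xm with 3xp were then 1 to 15 and of 3xm with 4x 1 to 8, all higher.

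**Figure D3:**
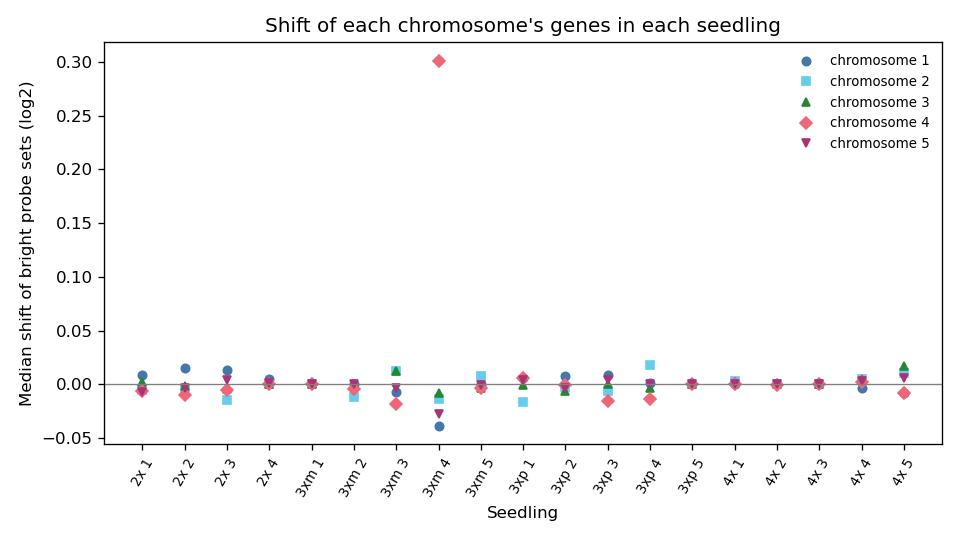
Median shift (log2, y axis) of the brighter probe sets in each seedling (x axis), relative to the median over all seedlings. Points are coloured and shaped by chromosome, for the 5 nuclear chromosomes. Chromosome 4 of seedling 3xm 4 lies at 0.301, while the largest shift of any other seedling is 0.0179 and the other chromosomes of 3xm 4 lie between −0.0388 (chromosome 1) and −0.00829 (chromosome 3).

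Seedlings from crosses between ploidies can carry unequal numbers of single chromosomes, so the median shift of each chromosome was taken in each seedling. Genes of chromosome 4 were higher in seedling 3xm 4 by 0.125 as a median and 0.164 as a trimmed mean. Of the 95 medians of 5 chromosomes in 19 seedlings 67 were exactly 0, because each array is itself the reference median of 5.7 to 9.1% of its probe sets, so medians cannot show small shifts. By trimmed means the other chromosomes of 3xm 4 lay between −0.0352 and −0.015, and no chromosome of another seedling shifted by more than 0.0124. Over the 512 brighter probe sets of chromosome 4 the shift was 0.301, with −0.0388 on chromosome 1 and −0.0272 on chromosome 5 of the same seedling. Of these probe sets 78.7% lay above their median over all arrays, after centring on all bright probe sets, against 41.9% on its other chromosomes. Of 19 windows of 100 neighbouring genes along chromosome 4, 18 were above 0 and in 16 this seedling was the highest of the 19. No difference between group means of the trimmed shifts passed an exact two-sided permutation test. For chromosome 4 of 3xm against 2x it was 0.0332 (exact p = 0.738, adjusted p = 0.915 over 20 tests). Chromosome identities come from locus names in the TAIR10.1 assembly.

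RNA quality was read from control probe sets on each array. The difference between 3' and 5' probe sets of the actin, GAPDH and ubiquitin controls was −0.242 ± 0.081 (SD, n = 5) in tetraploids and −0.233 ± 0.0886 (SD, n = 4) in diploids (exact permutation p = 0.881). This difference followed the replicate number: it was lowest in replicate 1 in all 4 groups, and numbers held a share of 0.703 of its spread within groups (permutation p = 0.00723, adjusted p = 0.0181 over 5 measures). For the median log2 value of an array the share was 0.793 (permutation p = 0.00077, adjusted p = 0.00385). Poly-A spike-in controls, added to the RNA before labelling, differed by −0.269 between tetraploids (5.42 ± 0.122, SD, n = 5) and diploids (5.69 ± 0.147, SD, n = 4) (exact permutation p = 0.0238, adjusted p = 0.143 over 6 comparisons). The 25S rRNA control probe set differed from 2x by 0.341 in 4x (exact permutation p = 0.119), 0.204 in 3xm (0.421) and 0.148 in 3xp (0.54). It was lowest in seedling 2x 1 (10.55). Whether it is related to the plastid-encoded genes, which also stood higher in these groups, was not tested. Tetraploid seedlings lay closer to their own group than either triploid, with a difference in median distance of 0.0303 for 3xm (exact permutation p = 0.00794, adjusted p = 0.0476) and 0.0246 for 3xp (exact permutation p = 0.0159, adjusted p = 0.0477). Each distance is taken from the other seedlings of the group, so distances within a group are not independent and these p-values are only a guide. Seedling 3xm 4, at 0.199, also enters the reference of the other 3xm seedlings. The median SD of a probe set within a group was 0.152 in 2x, 0.179 in 3xm, 0.175 in 3xp and 0.146 in 4x. With 1 seedling of 3xm left out, that of 3xm ranged from 0.148 to 0.184.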

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

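Of the tests below, those on an array-wide technical difference and on root markers moving alike were chosen only after the result was seen, as was the refit without seedling 3xm 1. The tests on bright probe sets of chromosome 4 were written after the shifts of whole chromosomes were seen but before the bright values were.

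Genes of chromosome 4 lay 0.125 higher in seedling 3xm 4, far from the other maternal-excess triploids. The tables argue against clusters of coexpressed genes, since 78.7% of the bright probe sets of chromosome 4 lay above their median, and against an array-wide technical difference, which acts on probe sets of every chromosome: those of chromosome 4 stood 0.328 above the other bright probe sets of that array, and the highest of 10000 random sets matched on number and brightness stood 0.0472 above. An extra copy of chromosome 4 may be the cause: the bright shift of 0.301 passed the bound set for it, though it is below the log2 ratio of 0.415 for 4 copies over 3. Seedling 3xm 4 was also far from its own group outside chromosome 4, by a root mean square of 0.555 where the next seedling, 3xp 5, had 0.383, and its median distance from its group was 0.199; a chromosome count was not used here.

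Genes higher in both 4x and 3xp, such as AT3G15450, AT2G20670, SIS and AT5G60680, were weighed as a pattern. A response to handling was not tested as a cause. The 2 measured handling-response genes, too few for a list test, had medians of 1.02 in 4x and 1.83 in 3xp. The amount of RNA labelled was tested with the poly-A spike-in level as a covariate. Of the 218 calls of 4x minus 2x, 100% kept an unadjusted limma p under 0.05, the bound set beforehand. That bound is looser than the one that picked these calls, so it decides little. Differences were 0.8 to 1.18 times their former value (0.727 to 1.31 without 3xm 1, the seedling with the highest spike-in level). Their median size was 0.763 after 0.752 (0.778 without 3xm 1), and the median SE 0.152 after 0.144 (0.168 after 0.143). These sizes argue against the amount of RNA labelled as the whole cause, as far as a straight-line covariate can show it. An adjusted p under 0.05 was kept by 129 of the 218, by 80 without 3xm 1, and by 199 of 262 in 3xp minus 2x; of the 89 calls lost in 4x 63 had a smaller difference (median ratio 0.961) and 76 a larger SE (median ratio 1.08), and of the 63 lost in 3xp 32 and 58, so a part of the calls may depend on it. RNA quality stays open, because its covariate, the 3' to 5' difference, moved the typical difference by 0.0424 of its SE, so that the 100% of calls kept beside it decides nothing. A low sugar state stays open too. The 9 measured genes of branched-chain amino acid breakdown had medians of −0.0734 in 4x and 0.0918 in 3xp. Their spread over genes gave an SE of 0.0299 and 0.0455, which leaves out the variation between seedlings. By that error the value in 3xp was too near the bound of 0.1 to decide. Genome copies, which the design varies, remain a possible biological explanation that stays open. The named genes did not rise in order of copies. Differences from 2x in 3xm, 3xp and 4x were 1.78, 3.38 and 2.53 for AT3G15450 and 1.90, 2.66 and 2.21 for AT2G20670. They were 0.97, 2.12 and 1.77 for SIS and 1.32, 1.89 and 1.68 for AT5G60680. None of these genes passed between the triploids, and as top genes they do not decide for the pattern.

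Root markers were higher in 4x than in 2x, by a median of 0.847 over EXPA7, EXPA18 and PYK10. A larger share of root in the harvested seedlings may explain it, as the median passed the bound of 0.3 set beforehand. If a larger share raised all root markers alike, the differences between them would stay the same. This is an assumption, since PYK10 read far brighter than both expansins. EXPA18 minus PYK10 was −4.71 in 4x and −5.59 in 2x, a change of 0.889 (exact permutation p = 0.0476, adjusted p = 0.0952). EXPA7 minus PYK10 was −5.43 and −6.05, a change of 0.622 (exact permutation p = 0.262). That test leaves the explanation open, with 3 markers measured. A change of root genes with genome copies also stays open and was not tested.

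Single seedlings far from the rest of their group were AT3G01260 in 3xp 3 (3.62), AT2G23910 in 4x 4 (3.49), AT5G62210 in 3xm 4 (8.02) and AT5G02180 in 3xp 5 (5.38). The same held for AT1G23205 in 4x 3 (6.09), 245668_at in 2x 1 (4.40) and AT1G80720 in 2x 1 (7.05) and 3xm 4 (6.38). Chance alone sets apart about 1 in 20 groups, and 8 of the 164 groups checked for named probe sets had such a seedling.

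Of the 95 median shifts of chromosomes 67 were exactly 0 by the way the reference was made, so that almost any other value stands apart from its group. Apart from chromosome 4 in 3xm 4, such values carry no weight here. On chromosome 1 they were 0.00496 in 2x 3, −0.00146 in 3xm 4 and 0.00485 in 3xp 3, and on chromosome 2 0.00652 in 2x 3. Chromosome 3 had −0.000593 in 2x 3, −0.000371 in 3xm 1, 0.00132 in 3xp 3 and 0.00121 in 4x 1. Chromosome 4 had −0.0038 in 2x 2 and −0.00426 in 3xp 3. On chromosome 5 the shifts were −0.000593 in 2x 3, 0.000144 in 3xp 3 and 0.00647 in 4x 1.

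The reciprocal triploids differed in 245668_at, by 0.88 (limma, adjusted p = 0.00731). Outside the comparisons, the poly-A spike-in probe sets of seedling 3xm 1 read 6.72, above the diploid mean of 5.69.

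Other splits of the same seedlings were counted, 100 per comparison including the real one. Chance is unlikely, though not excluded, for 4x minus 2x (1 split, the real one, called as many as the real 218, the highest other 35), 3xp minus 2x (1, real 262, highest other 116), 3xm minus 4x (1, real 17, highest other 2) and the trend (1, real 110, highest other 0). With 100 splits the share cannot fall below 1 in 100, and every comparison was examined in this way. The splits also take seedlings as exchangeable, although measures per array followed the replicate number. For 3xp minus the midpoint chance stays open: 2 of 100 splits, the real one included, reached the real 58, and the highest other called 103. That split put all 4 diploids with 4x 5 in the place of 3xp. Such splits mix diploids, tetraploids and triploids, so they do not test a departure from the midpoint alone. Few splits reached the real count in 3xm minus 2x (2, real 8, highest other 123), 3xm minus the midpoint (3, real 1, highest other 1) and 3xp minus 4x (1, real 5, highest other 0). Yet 985, 823 and 1105 probe sets had an unadjusted p under 0.05 there, below the 1137.3 expected by chance, and 0, 0 and 1 passed with only the compared groups fitted, so chance stays open for these 3. For 3xp minus 3xm, 5 of 100 splits called at least the real 1 and the highest other called 185, so chance stays open there too. Splits that call several times the real count point to a structure of the samples. In 3xm minus 2x that split put 2x 2, 2x 4, 3xm 1, 3xm 2 and 3xm 4 on one side, and in 3xp minus 3xm 3xm 3, 3xm 4, 3xm 5, 3xp 3 and 3xp 5.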

How the results depend on the processing

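Leaving out the seedling with higher chromosome 4 was chosen after the data were seen. Named calls in this section leave out ATG8C and JAL33, which come from the wider lists chosen afterwards. Of 66 calls of named genes, 1554 of 1848 values under alternatives kept the call, 294 lost it and 0 reversed direction. Unless said otherwise, the cause was not tested.

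Leaving out 1 seedling gave 77 to 382 calls in 4x minus 2x, 1 to 17 in 3xm minus 2x, 107 to 356 in 3xp minus 2x, 1 to 4 in 3xp minus 3xm, 6 to 56 in 3xm minus 4x, 2 to 5 in 3xp minus 4x, 0 to 1 in 3xm minus the midpoint, 17 to 77 in 3xp minus the midpoint and 25 to 226 in the trend. Lists passing were 1 to 3, 1 to 3, 1 to 1 and 0 to 2 in the comparisons with diploids (4x, 3xm, 3xp) and between triploids. Among lists that did not pass over all seedlings, medians turned and passed for the flavonoid list in 3xp (−0.351 without 2x 1; −0.351 to 0.337 over omissions) and the mitochondrial genes in 3xm (0.137 without 2x 3; −0.0293 to 0.137). Correlations of changes were 0.598 to 0.755 (3xm and 3xp), 0.562 to 0.701 (3xm and 4x) and 0.692 to 0.788 (3xp and 4x). The 3' to 5' difference of 4x minus 2x was −0.0458 to 0.0265 and the median SD of 3xm 0.148 to 0.184.

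With only the compared groups in the fit the counts were 451 (4x minus 2x), 0 (3xm minus 2x), 109 (3xp minus 2x), 0 (3xp minus 3xm), 1 (3xp minus 4x) and 0 (3xm minus the midpoint). With eBayes trend and robust 3xm minus the midpoint had 0. Array weights gave 1017 (4x minus 2x, 466 higher and 551 lower), 423 (3xp minus 2x), 45 (3xm minus 4x), 88 (3xp minus the midpoint) and 683 (trend, 296 rising and 387 falling). With 1 probe set per gene, where fewer are tested by construction, the counts were 99 (4x minus 2x), 5 (3xm minus 2x), 123 (3xp minus 2x), 0 (3xp minus 3xm), 7 (3xm minus 4x), 1 (3xp minus 4x), 0 (3xm minus the midpoint), 19 (3xp minus the midpoint) and 51 (trend). A fold of at least 1.5, which removes smaller changes by construction, left 163 (3xp minus 2x), 11 (3xm minus 4x), 0 (3xm minus the midpoint) and 29 (trend), and of the named calls ended those of AT3G17130 and AT1G65920 (3xp minus 2x), 251436_at (3xm minus the midpoint) and AT1G80720 (3xp minus the midpoint). The trend had 223 calls with 3xm and 186 with 3xp as the triploid. Without the seedling with higher chromosome 4 the counts were 382 (4x minus 2x), 3 (3xp minus 4x) and 226 (trend).

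With an estimated correlation 0 lists passed in each of the 4 comparisons, and without dim probe sets 0 passed in 3xp minus 3xm. With 2 different diploids in each comparison the correlations of changes were 0.307 (3xm and 3xp), 0.269 (3xm and 4x) and 0.434 (3xp and 4x); these share no arrays and rest on fewer diploids each, and the effects of both were not separated. The largest chromosome shift, 0.125, was 0.164 with a trimmed mean, 0.273 without dim probe sets and 0.27 in windows. Near background a fall or a shift is compressed, which limits what dim probe sets can show, and without them 254 probe sets were called in 4x minus 2x and 291 in 3xp minus 2x.

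Seedlings were not taken as paired by replicate number, since not every pair correlated above 0.1: deviations of seedlings with the same number correlated by 0.0513 on average (27 pairs, 12 above 0.1, from −0.375 to 0.435) against −0.0121 for different numbers, and 6 of 19 seedlings correlated best with their own number. Yet the 3' to 5' difference and the array median followed the number (adjusted permutation p = 0.0181 and 0.00385, tests chosen after the data were seen). The number may thus mark a shared step of preparation, which would not need every pair to correlate. On the third principal component (10.8% of the variance) seedlings 3xp 5 (30.64), 4x 5 (23.08) and 3xm 5 (15.6) scored highest, followed by 4x 2 (6.05). The diploids had no replicate 5, so in comparisons with 2x these seedlings had no diploid of their number. With a replicate block the counts were 2 (3xp minus 3xm), 28 (3xm minus 4x), 8 (3xp minus 4x) and 0 (3xm minus the midpoint), and 1 list passed in 4x minus 2x, the root markers having an adjusted p of 0.081. The replicate block moved no other count of calls by over 1.5 times. With it 57 of the 66 named calls passed and 9 did not: AT4G11190, AT5G15950 and AT1G32690 (4x minus 2x), AT1G23205 (3xp minus 2x), 251436_at (3xm minus the midpoint), STZ, AT5G17270 and AT1G80720 (3xp minus the midpoint) and AT5G19120 (trend).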

Other observations

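The wider gene lists in this part were chosen only after the result was seen.

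Autophagy genes, namely the measured ATG8 genes, whose products coat autophagosomes, and ATG3, were higher as a set in 3xp than in 2x. All 10 had a positive difference (median 0.364; camera, adjusted p = 1.51e-06 with the preset correlation, adjusted p = 0.207 with an estimated correlation), and ATG8C rose by 0.48 ± 0.0905 (limma, adjusted p = 0.0102), a call that ended without 2x 1 (adjusted p = 0.0576) and at a fold of at least 1.5. In 4x the median was 0.28 (adjusted p = 0.000361, with an estimated correlation adjusted p = 0.509), and in 3xp against 3xm 0.261 (adjusted p = 3.18e-05, with an estimated correlation adjusted p = 0.149), with no member passing by limma. The 33 pathogen and wound genes were higher in 4x (median 0.202; adjusted p = 0.00499, with an estimated correlation adjusted p = 0.509), where the lectin gene JAL33 rose by 0.88 ± 0.209 (adjusted p = 0.0497) and lost its call in 15 of the 19 omissions. Their medians were 0.143 in 3xm (adjusted p = 0.00085, with an estimated correlation adjusted p = 0.51) and 0.0685 in 3xp (adjusted p = 0.00637, with an estimated correlation adjusted p = 0.548), where STZ passed. Of 28 families sharing a symbol, 3 passed in 4x (ATG higher, UBP and UGT lower), 0 in 3xm and 2 in 3xp (ATG higher, UBP lower), each against 2x, and 0 did with an estimated correlation. The ATG family overlaps the autophagy list. The higher chromosome 4 of seedling 3xm 4 enters each comparison with 3xm.

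Between the triploids, 28 histone and chromatin genes were lower in 3xp than in 3xm (median −0.0993; camera, adjusted p = 0.000268, with an estimated correlation adjusted p = 0.149). So were 29 genes of mitosis and replication (median −0.14; adjusted p = 0.00419, with an estimated correlation adjusted p = 0.419) and 26 of DNA repair (median −0.0508; adjusted p = 0.039, with an estimated correlation adjusted p = 0.149). The 20 cold and dehydration genes were higher (median 0.163; adjusted p = 0.0439, with an estimated correlation adjusted p = 0.499). No member of these 4 lists passed by limma. The other themed lists did not pass in any of the 4 comparisons.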
